A study of Mus musculus with 2 samples.

How the data were processed

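Nuclear RNA was measured in 2 single-nucleus libraries of mouse hippocampus, 1 from a mouse heterozygous for a knockout of Capza2 and 1 from a wild-type mouse. Per the labels' protocols, nuclei were released from the tissue with a Dounce homogenizer, cleaned by density centrifugation and made into droplet libraries with the 10x Genomics 3' v3 chemistry, in which each transcript is read near its 3' end and carries a unique molecular identifier (UMI). The deposited matrices hold raw UMI counts per gene and barcode, and per the file headers and the submitters' processing notes the authors made these counts with Cell Ranger 7.1.0 on the mouse genome mm10. Every deposited barcode carried at least 500 UMIs. The heterozygote matrix held 7801 barcodes and the wild-type matrix 6512, each over 32285 genes. No table of cell types was used here, so classes of nuclei were rebuilt from the counts.

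Gene identifiers were compared with the GENCODE M21 annotation of GRCm38, and 32235 of 32285 were found there. Coordinates are those of that annotation.

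Everything below was computed here, with Python 3.11.15, scanpy 1.11.5, leidenalg 0.10.2, scipy 1.17.1 and numpy 2.4.6. The filters, comparisons, gene lists, cell type markers and the rule for naming genes were chosen before the data were examined, and the checks of explanations given at the end were chosen later. Barcodes with at least 500 genes detected and at most 5% mitochondrial UMIs were kept. Doublets, droplets with more than 1 nucleus, were called in each library with Scrublet at an expected rate of 0.8% per 1000 barcodes. The automatic threshold marked 10.94% of the wild-type nuclei, and those 703 nuclei were removed. In the heterozygote library the automatic threshold marked 0.0416%, under the set minimum of 0.5%, so the highest scores up to the expected 5.769% were removed instead (416 nuclei). The share removed as doublets therefore differs between the libraries, and settings with like shares were added as alternatives. This left 6795 heterozygote and 5721 wild-type nuclei.

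Counts were scaled to 10000 UMIs per nucleus and log-transformed. The nuclei of both libraries were clustered together without integration on 2000 variable genes and 30 principal components, with 15 neighbours and Leiden resolution 1. Capza2, mitochondrial, ribosomal protein, Xist, Tsix and Y-linked genes were kept out of the variable genes. A cluster was named "like" the cell type whose markers had the highest mean log2 ratio against the other clusters, if that was at least 1 and at least 3 markers were detected. The remaining clusters were compared among themselves for the regional excitatory types, with a mean of at least 0.5. Clusters whose mean doublet score was at least 2 times that of all nuclei, and whose median UMI count was above that of the largest cluster of their type, were set apart as mixed. This rule was chosen and revised after the data were examined, and it took 5.05% of the heterozygote and 2.10% of the wild-type nuclei. Clusters 19, 20, 21, 32 and 36 had none of these names but at least 3 general excitatory markers detected. They were called excitatory with no regional name and were compared by number only. Cluster 12, of shallow nuclei led by hemoglobin genes, stayed unnamed.

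With 1 library per genotype there is no replicate check, so no test between genotypes, p-value or count of changed genes is given. Shares carry exact binomial (Clopper-Pearson) intervals and UMI counts exact Poisson intervals. Ratios of shares or of counts scaled to a common total (CPM) carry exact conditional binomial intervals, all at 95%. These intervals cover counting error only, and not the spread between mice or preparations. Those of UMI counts also leave out the spread between nuclei, so a gene carried by few nuclei can rank high. For expression, UMIs were summed per library and class in the 8 classes with at least 200 nuclei in each library, and the log2 ratio of CPM (heterozygote over wild type) was computed for genes with at least 200 UMIs over both libraries. In each class the 5 highest and 5 lowest genes were named, ranked by the interval bound nearest to 0. Across classes the 10 highest and 10 lowest by median ratio were named, among genes over the floor in at least 4 classes and of the same sign in each. Mitochondrial, Xist, Tsix and Y-linked genes were left out of both rankings. Up to 4 members of each gene list are named, and Capza2, Capza1 and Capzb are always given. Between 0 and 6 gene models with no symbol of their own were passed over per class and direction, among them AC149090.1 in every class, and across classes 4 among the highest and 1 among the lowest.

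Of the 21 gene lists fixed, 20 are described here, and not every gene that the naming rule picked is given. They cover actin capping and its regulators, the Arp2/3 and WAVE complexes, actin filaments and their turnover, the dynactin and WASH complexes, glutamate receptors and the postsynaptic density, presynaptic release, the GABA synapse, activity-regulated genes, voltage-gated ion channels, neurodevelopmental disorder genes, and axon guidance and cell adhesion. They also cover mitochondrially encoded transcripts, the nuclear-encoded respiratory chain, cytosolic ribosomal proteins, heat shock and stress, myelin, homeostatic microglia, activated microglia, reactive astrocytes, and astrocyte glutamate and potassium handling. A list with at least 3 members over the floor is described by its median log2 ratio and the percentile of that median among 10000 random lists of the same size matched on mean expression. A median under the 2.5th or over the 97.5th percentile is called outside the random range. Of 136 pairs of list and class over all lists, 34 lay outside, a range that leaves out 5% of random lists. This describes the 2 libraries and is not a test of genotype.

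The expression steps were tested on simulated data, with counts drawn for the real genes of each class and 200 genes drawn to change by a known log2 fold. Such draws test counting error alone, and not the spread between mice, preparations or nuclei. They therefore cannot show that the genes named in the real data were truly changed. In the dentate granule comparison (9849 genes), 95.4% of true ratios lay within their intervals. All 20 genes picked in that comparison had truly been changed, though this is more picks than the naming rule takes per class. There the interval left out 0 for 92.1% of the 63 genes changed by 0.5 log2, and for 100% of those changed by 1 or 2. In the microglia comparison (657 genes) that share was 78.0% of 59 genes at 0.5 log2. Intervals for the ratio of 2 shares covered the true value in 96.2% to 98.1% of 2000 draws over 4 pairs of shares.

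Alternatives for the shares were at least 200 or 1000 genes, at most 1% or 10% mitochondrial UMIs, doublets kept, resolution 0.5 or 2, 3000 variable genes, clustering each library separately, thinning nuclei to 1000 UMIs, and neurons or non-neuronal nuclei as the denominator. Alternatives for expression were a shift by the median ratio, doublets kept, thinning, at least 1000 genes, at most 1% mitochondrial UMIs and the mean of CPM over nuclei. For Capza2, all barcodes and equal makeup were also tried, and for the lists a floor of 50 UMIs and a pool without mitochondrial, ribosomal protein and sex-linked genes. Chosen after the data were examined were the expected and the higher doublet rate in both libraries, for expression also the largest cluster of each class and resolution 2, and the use of the expression alternatives for the lists and for Capza2 over all nuclei. Ddit3, a symbol shared by 2 identifiers, and Clec7a, with no entry under that symbol, were left out of their lists.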

Results

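Single-nucleus RNA sequencing of the hippocampus compared the makeup of cell populations between a Capza2 heterozygous knockout mouse and a wild-type mouse. Capza2 encodes an alpha subunit of capping protein, which binds the barbed ends of actin filaments, and the study concerns its role in neurodevelopmental disorders. Each genotype had 1 library, so every difference below is between 2 libraries and has no replicate check. The heterozygote library held 62702888 UMIs in 7801 barcodes, with a median of 5444 UMIs and 2482 genes per barcode. The wild-type library held 58701532 UMIs in 6512 barcodes, with medians of 6789 UMIs and 2827.5 genes. After filtering, 6795 heterozygote nuclei (median 5764 UMIs) and 5721 wild-type nuclei (median 6365 UMIs) were compared.

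Capza2 was lower in the heterozygote library, while over all nuclei its partner subunits lay closer to the wild-type level. Over all nuclei kept, Capza2 (ENSMUSG00000015733, GRCm38 chromosome 6, 17636234 to 17666972, plus strand) had 3757 UMIs in the heterozygote (95% interval 3638 to 3879) and 4032 in the wild type (3909 to 4158). This made 67.8 against 87.9 CPM, or 0.771 times the wild-type level (0.737 to 0.806; log2 ratio -0.38, -0.44 to -0.31). Capza1, the other broadly expressed alpha subunit, had a log2 ratio of -0.04 (-0.12 to 0.03), and Capzb, the beta subunit, -0.10 (-0.18 to -0.01). By class, Capzb was at -0.51 (-0.88 to -0.15) in CA3 pyramidal-like and -0.35 (-0.69 to -0.02) in inhibitory neuron-like nuclei, and in the other classes compared the intervals of Capza1 and Capzb held 0. In inhibitory neuron-like nuclei Capzb was at 0.16 after thinning to 1000 UMIs and at 0.09 in the largest cluster. No UMI of Capza3, known as a testis form, was found in either library. Capza2 was lower in 8 of 8 classes compared, with 5 intervals below 0. The ratio was lowest in oligodendrocyte-like nuclei (-0.59, -0.85 to -0.33), followed by subicular, entorhinal or cortical excitatory-like (-0.50), dentate granule-like (-0.48), CA1 pyramidal-like (-0.42) and inhibitory neuron-like nuclei (-0.39). It was -0.27 in CA3 pyramidal-like, -0.26 in astrocyte-like and -0.07 in microglia-like nuclei, whose intervals held 0. The 9 other genes over the floor within 2 Mb of Capza2 had a median log2 ratio of -0.01, from -0.55 for Met to 0.22 for Lsm8. The deleted part of the gene is not given in the sources used here, and a 3' tag outside it would check nothing about the allele. With every nucleus weighted alike the ratio over all nuclei was -0.15, and in nuclei thinned to 1000 UMIs it was 0.46 in the CA3 pyramidal-like and -1.18 in the subicular, entorhinal or cortical excitatory-like class. In the largest cluster of the latter it was -0.77, so the order of the classes depends on the setting.

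**Figure D1:**
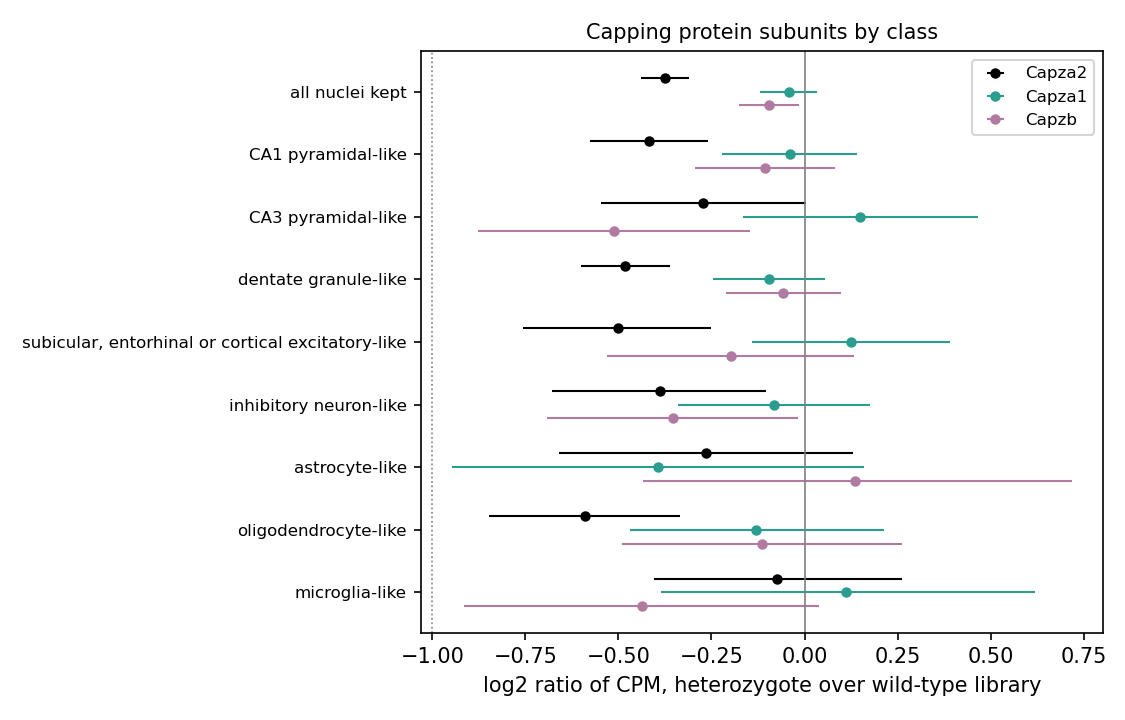
Log2 ratio of CPM (heterozygote over wild-type library) of Capza2, Capza1 and Capzb over all nuclei kept and in 8 classes, with 95% counting intervals as bars; the solid line marks 0 and the dotted line a log2 ratio of -1. Capza2 lies below 0 in every class, from -0.59 to -0.07.

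The comparison the study names is that of cell population proportions. Neuron-like nuclei made up less of the heterozygote library, 60.1% (59.0 to 61.3) of the nuclei kept against 70.0% (68.7 to 71.1). Non-neuronal nuclei made up more, 31.4% (30.3 to 32.6) against 27.1% (26.0 to 28.3). Among neurons the classes went both ways. Dentate granule-like nuclei had the higher share in the heterozygote library, 30.1% against 25.6% (1.18 times, 1.099 to 1.26). CA1 pyramidal-like nuclei were at 11.3% against 16.0% (0.708 times, 0.642 to 0.780), inhibitory neuron-like nuclei at 4.68% against 6.71% (0.697 times, 0.599 to 0.811), and subicular, entorhinal or cortical excitatory-like nuclei at 5.61% against 8.63% (0.649 times, 0.567 to 0.744). CA3 pyramidal-like nuclei were at 3.16% against 3.55%, with an interval of the ratio that held 1 (0.733 to 1.09).

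Rarer neurons were measured with less precision. Hilar mossy-like nuclei numbered 10 against 29 (0.290 times, 0.126 to 0.613), and Cajal-Retzius-like nuclei 37 against 30 (1.04 times, 0.624 to 1.74). CA2 pyramidal-like nuclei were at 1.88% against 3.22% (0.586 times, 0.464 to 0.738), but their ratio turned above 1 under 5 alternative settings. The subicular, entorhinal or cortical excitatory-like ratio also turned when each library was clustered separately (log2 0.55). The 5 excitatory clusters with no regional name, numbers 19, 20, 21, 32 and 36, each held a lower share of the heterozygote library, from 0.310 times for cluster 36 to 0.583 times for cluster 19, with intervals below 1 except for cluster 32. Several leading gene models of cluster 36 also led the inhibitory neuron-like cluster 14, so the name of cluster 36 is uncertain.

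Oligodendrocyte-like nuclei, which make myelin, were at 16.6% of the heterozygote and 14.0% of the wild-type library (1.19 times, 1.08 to 1.30). Against non-neuronal nuclei alone this ratio was 1.02 (0.935 to 1.12), so the higher share went with the lower share of neurons. Microglia-like nuclei were at 4.67% against 3.92% (1.19 times, 1.00 to 1.42), and astrocyte-like nuclei at 4.92% against 4.68% (1.05 times, 0.891 to 1.24). Oligodendrocyte precursor-like nuclei were at 2.69% against 2.94% (0.917 times, 0.740 to 1.14). Of non-neuronal nuclei alone they made up 8.57% against 10.8% (0.791 times, 0.638 to 0.981). Choroid plexus epithelium-like nuclei numbered 63 against 14 (3.79 times, 2.10 to 7.32). This epithelium lies in the ventricles beside the hippocampus, and at resolution 2 the ratio was 2.07. The mean doublet score of this cluster was 2.16 times that of all nuclei. As the only cluster named so, it could not be set apart as mixed, so doublets may be among its nuclei. No value was obtained with each library clustered separately or with thinning before clustering. Ratios of the committed oligodendrocyte precursor-like (1.40), endothelial-like (0.842), pericyte or smooth muscle-like (1.28), fibroblast-like (1.36) and perivascular macrophage-like nuclei (0.842) had intervals that held 1, but with each library clustered separately the endothelial-like log2 ratio was -1.53, against -0.25. A share is relative, so a higher share of 1 class lowers all the others, and 7.56% of the heterozygote barcodes against 1.35% of the wild-type barcodes were under the filters.

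**Figure D2:**
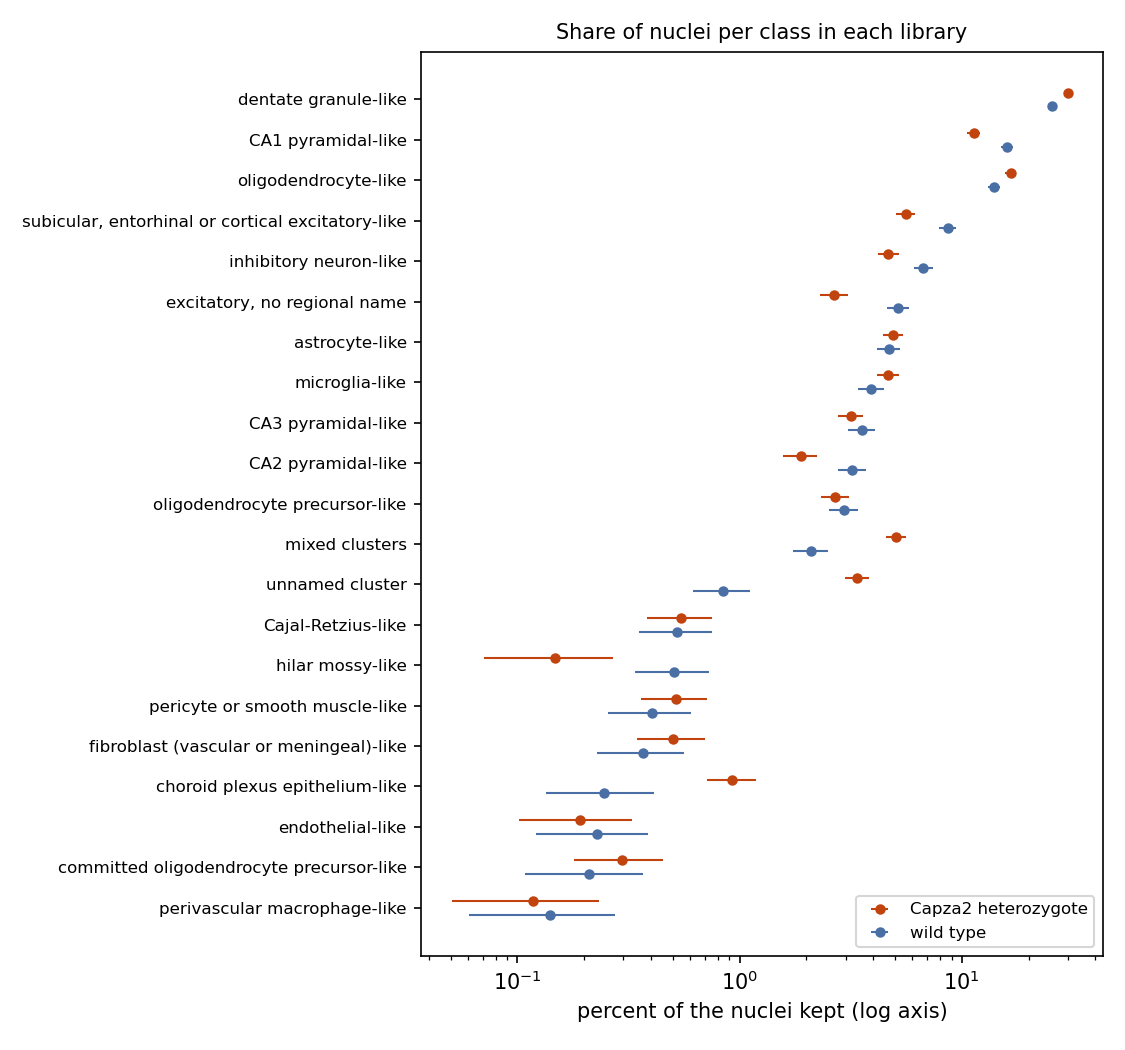
Percent of the nuclei kept in each class (log axis) in the heterozygote and wild-type libraries, with exact binomial 95% intervals as bars. Dentate granule-like nuclei were at 30.1% against 25.6% and CA1 pyramidal-like nuclei at 11.3% against 16.0%.

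Expression was then compared class by class, with mitochondrial, Xist, Tsix and Y-linked genes left out of the rankings. Across classes, Ttr stood highest in the heterozygote library: it encodes transthyretin, a thyroid hormone carrier made in quantity by the choroid plexus. Its median log2 ratio was 1.77, a fold of 3.42, and it was higher in 8 of 8 classes (1.33 to 2.13). Ttr was at 1.31 to 1.49 UMIs per nucleus in the 8 heterozygote classes and at 0.271 to 0.459 in the wild-type classes. Next came Enpp2 (0.54), which encodes the lysophospholipase autotaxin, Hspa5 (0.43), the endoplasmic reticulum chaperone BiP, and Sema5a (0.43), a guidance semaphorin. Trpc6 (0.41), a cation channel, Nptx1 (0.40), a pentraxin of excitatory synapses, the transcription factor gene Pou3f3 (0.38), Sgce (0.38), Tmem144 (0.37) and Rab10os (0.36) completed the highest 10. Thinned to 1000 UMIs, the median of Tmem144 was -0.27. Sema5a and Trpc6 were among the leading genes of the dentate granule-like clusters. Of the genes ranked, the lowest across classes were Plpp1 (-0.51), a lipid phosphate phosphatase, Pdzrn3 (-0.51), a ubiquitin ligase, and Castor2 (-0.50). Efnb2 (-0.50), which encodes ephrin-B2, and Gfod2 (-0.49) came next. Bcorl1 (-0.45), Sgcz (-0.44), the intraflagellar transport gene Ift88 (-0.44), Capza2 (-0.40) and Slc22a14 (-0.39) followed.

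**Figure D3:**
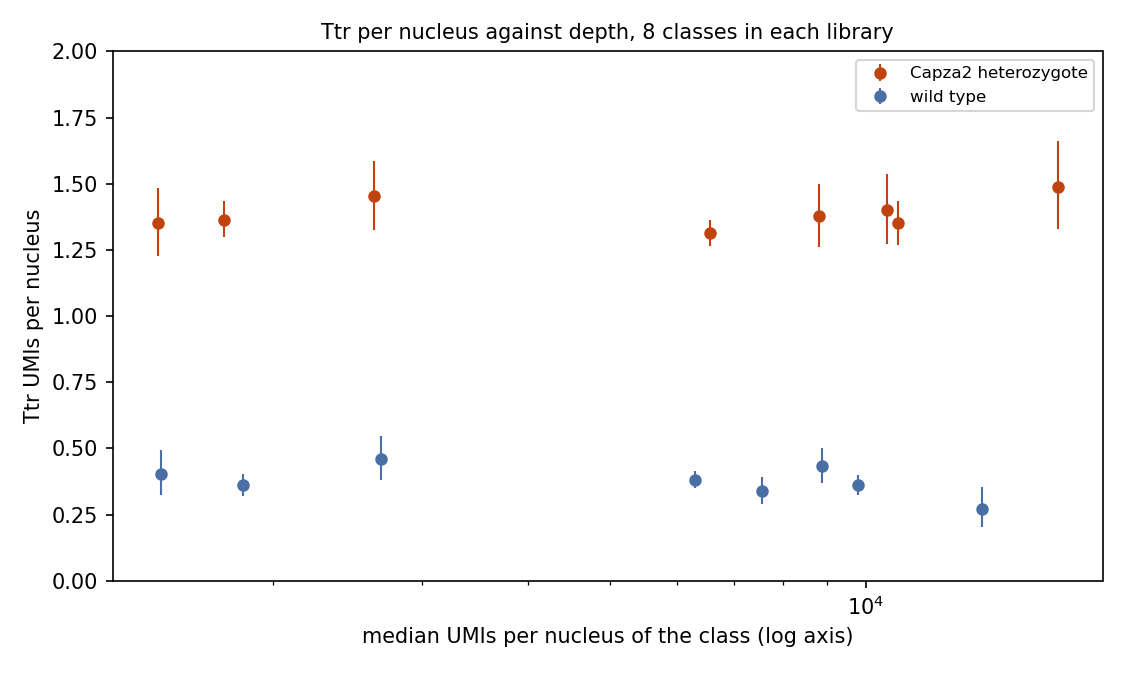
Ttr UMIs per nucleus (vertical axis) against the median UMIs per nucleus of the class (log axis) in 8 classes of each library, with exact Poisson 95% intervals as bars. The heterozygote classes lie between 1.31 and 1.49 and the wild-type classes between 0.271 and 0.459.

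Dentate granule-like nuclei, the largest class (2046 heterozygote and 1465 wild-type nuclei), had higher Hspa5 in the heterozygote library, with 86.7 against 45.4 CPM (log2 0.93, 0.78 to 1.08). Apool (0.98), which encodes a protein of the mitochondrial inner membrane, Hbb-bs (0.93), an adult beta globin, and Chgb (0.65), the secretory granule protein chromogranin B, were also higher, beside Ttr (1.78). The lowest genes were Dpp10 (-0.75), an auxiliary subunit of Kv4 potassium channels, Sgcz (-0.62), Traip (-0.72), Kcnmb2 (-0.76), a subunit of calcium-activated potassium channels, and Slc25a25 (-0.62), a mitochondrial carrier. Hemoglobin UMIs summed over 4 genes were also higher in this class, at 0.210 against 0.0997 per nucleus. Cluster 0 held 51.8% of the heterozygote and 69.3% of the wild-type nuclei of the class and cluster 1 the rest, and thinned to 1000 UMIs the ratio of Traip was 0.02.

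In CA1 pyramidal-like nuclei the 5 lowest genes were at least 3.46-fold lower. Unc5d, a netrin receptor, was at 16.2 against 117 CPM, 7.19-fold lower, and Efna5, which encodes ephrin-A5, was 6.25-fold lower. Lrrtm3 (4.12-fold), which encodes a synaptic adhesion protein, Dpp10 (3.46-fold) and Pcdh15 (3.46-fold), a protocadherin gene, were lower as well. The highest were Apool (log2 2.02), Ttr (1.74), the homeobox gene Prrx1 (1.62), Stxbp6 (0.97) and Cdh10 (0.54), a cadherin gene. The fixed axon guidance and cell adhesion list, which holds Unc5d and Efna5, was at -0.04 in this class, inside the random range (7.53, 18 of 32 members lower). The 5 lowest genes were concentrated in few nuclei: in the wild-type library at least 88.1% of the UMIs of each lay in the tenth of the nuclei with the most of it, where 44.9% was typical of genes with 405 to 4893 UMIs over both libraries. Cluster 3 held 73.2% of the heterozygote and 64.5% of the wild-type nuclei of the class and cluster 7 the rest. Within cluster 3 alone Dpp10 was at 0.17, Stxbp6 at -0.21, Unc5d at -0.68 and Efna5 at -1.08, while Lrrtm3 stayed at -1.78 and Pcdh15 at -1.39. With at least 1000 genes per nucleus Dpp10 was at 0.10, Unc5d at -0.44, Lrrtm3 at -0.52 and Efna5 at -0.68, so the size of the differences in Dpp10, Unc5d, Lrrtm3 and Efna5 depends on the nuclei compared. In CA3 pyramidal-like nuclei the highest were Ttr (2.13), Maml3 (1.204), a Notch coactivator gene, Cdh18 (0.93), Cdh10 (0.53) and Ifi203 (0.72), an interferon-inducible gene. The lowest there were the contactin gene Cntn4 (-1.47), Kirrel3 (-1.43), which encodes a synaptic adhesion protein, Nnat (-0.84), Fbxl7 (-0.76) and Limch1 (-0.85). Thinned to 1000 UMIs, Ifi203 was at -0.08 and Fbxl7 at 0.42, and with the expected doublet rate in both libraries Maml3 was at -0.03, Cdh18 at 0.06 and Kirrel3 at -2.43.

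Inhibitory neuron-like nuclei had higher levels of genes found in excitatory neurons. Tafa1 was at 398 against 47.0 CPM (log2 3.08, 2.86 to 3.31), Hs3st4 at 2.45, Foxp2 at 2.66, the synaptic vesicle gene Sv2b at 1.86 and Arpp21 at 1.51. Summed markers of other classes were higher too, the oligodendrocyte list by more (0.75, 0.61 to 0.90) than the excitatory list (0.40, 0.31 to 0.50), and the inhibitory list was lower (-0.24, -0.25 to -0.22). These ratios depended on how doublets were treated: with doublets kept Tafa1 was at 0.39, Hs3st4 at 0.44, Foxp2 at 0.68, Sv2b at 0.36 and Arpp21 at 0.16, and with the expected doublet rate in both libraries the 5 genes lay between 0.21 (Sv2b) and 0.61 (Foxp2). Among the lowest, Egr1 (-1.05) is an activity-regulated transcription factor gene, Pde3a (-0.80) encodes a phosphodiesterase, Ndnf (-0.82) marks neurogliaform cells and Wnt5b (-0.86) is a Wnt ligand gene, with Tnfaip8l3 at -0.89. In subicular, entorhinal or cortical excitatory-like nuclei the highest were Npy (2.05), which encodes a neuropeptide of interneurons, Ttr (1.77), Glis3 (1.94), Zbtb20 (1.55) and Trps1 (1.54). Glis3 was in the dentate granule marker list and Trps1 in the CA3 pyramidal list, and the summed dentate granule (0.54, 0.45 to 0.63), astrocyte (0.22) and inhibitory lists (0.20) were higher in this class. The lowest were Cpa6 (-1.37), Erbb4 (-1.01), the neuregulin receptor, Pde1c (-0.94), Ptprm (-0.83) and Efnb2 (-0.79). Npy rested on 2 heterozygote nuclei with at least 3 of its UMIs, and with the higher doublet rate in both libraries it was at -0.03. With doublets kept Glis3 was at 0.62 and Zbtb20 at 0.65, and in the largest cluster of the class Trps1 was at 0.60. With at least 1000 genes per nucleus Cpa6 was at -0.39.

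Besides Ttr (1.66), astrocyte-like nuclei were highest in the neuronal genes Epha6 (1.51), Cntnap2 (1.38), Kcnip4 (0.85) and Opcml (0.99), and the excitatory marker list, summed, was at 0.43 (0.28 to 0.58) in them and the oligodendrocyte list at 0.47 (0.25 to 0.70). Cntnap2 was at -0.35, Kcnip4 at -0.09 and Epha6 at 0.46 with every nucleus weighted alike, and Opcml at 0.32 with at least 1000 genes per nucleus. The lowest were Lhfp (-1.06), Fgf12 (-0.88), Nhsl1 (-0.60), the netrin receptor gene Dcc (-0.59) and Frmd4a (-0.44). Oligodendrocyte-like nuclei were highest in Ttr (1.94), Pcp4 (0.76), Spcs1 (0.82), a signal peptidase subunit, Mal (0.53), a myelin proteolipid, and Jun (0.79), and lowest in Nckap5 (-0.87), Synpr (-0.65), Csmd2 (-0.70), Frmd4a (-0.63) and Cacna2d3 (-0.74), a calcium channel subunit. In microglia-like nuclei Ttr (1.79), the ATP synthase gene Atp5l (0.79), Lsamp (0.68), Myo9a (0.69) and Ptma (0.63) were highest. Sdk1 (-1.06), Fat3 (-0.83), Nav2 (-0.52) and Dlc1 (-0.71) were among the lowest. Lsamp turned below 0 under 5 alternatives, to -0.41 with doublets kept.

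Gene lists tied to actin showed small differences. The actin capping list was at -0.26 in astrocyte-like nuclei (percentile 0.70 among random lists, 5 of 7 members lower), with Tmod2 at -0.41 and Carmil1 at -0.37. The list holds Capza2, whose own value, with an interval that held 0, is this median, and with a floor of 50 UMIs the median was inside the random range. It lay between -0.07 and 0.01 in the other 7 classes, inside the random range. Medians of the Arp2/3 and WAVE complexes, which nucleate branched actin, ran from -0.05 to 0.10, those of actin filaments and their turnover from -0.09 to 0.06, and those of the dynactin and WASH complexes from -0.14 to -0.0039. None of these medians lay outside the random range.

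Mitochondrially encoded transcripts were lower in the heterozygote library, with medians from -1.08 in inhibitory neuron-like to -0.22 in microglia-like nuclei, where the percentile was 3.06; the other 7 classes lay under the 2.5th percentile, but not in 2 of 10 settings for astrocyte-like and 1 of 10 for subicular, entorhinal or cortical excitatory-like nuclei. Lowest in CA1 pyramidal-like nuclei were mt-Nd4l (-1.43) and mt-Nd1 (-1.20), subunits of complex I. Summed over all nuclei kept, these transcripts were at 4.69 against 7.47 UMIs per nucleus. The libraries are of isolated nuclei, so carry-over of these transcripts in each preparation cannot be told apart from a difference in expression. The nuclear-encoded respiratory chain went the other way in dentate granule-like (0.19, 27 of 29 members higher), astrocyte-like (0.19, 13 of 15) and oligodendrocyte-like nuclei (0.16, 24 of 28), with Cox8a at 0.44 and Ndufb9 at 0.43 in the first, and lay inside the random range elsewhere (-0.14 to 0.12). Cytosolic ribosomal protein genes were higher in dentate granule-like (0.20, 76 of 81 members), astrocyte-like (0.20, 47 of 57), oligodendrocyte-like (0.25, 77 of 79) and microglia-like nuclei (0.19, 27 of 38; inside the random range in 1 of 11 settings). In CA1 pyramidal-like (0.05) and subicular, entorhinal or cortical excitatory-like nuclei (0.04) they also lay above the random lists, in CA3 pyramidal-like nuclei below them (-0.18, 47 of 54 members lower; inside in 3 of 10 settings), and in inhibitory neuron-like nuclei inside (-0.04).

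Synaptic lists were close to 0 in most classes. Presynaptic release was at 0.08 in dentate granule-like nuclei (percentile 99.8, 20 of 29 members higher), with Unc13b at 0.28 and Cplx2 at 0.25, and at 0.14 in astrocyte-like nuclei (98.3). These medians lay inside the random range in 2 of 11 and 5 of 11 alternative settings. The GABA synapse list was at 0.07 in dentate granule-like (97.9, 12 of 19), and at 0.12 in subicular, entorhinal or cortical excitatory-like nuclei (99.95, 12 of 16), with the receptor subunit gene Gabra2 at 0.44, but lay inside the random range in 5 of 11 and 3 of 11 settings. In the second class the inhibitory markers were higher as well (0.20, 0.12 to 0.28). Glutamate receptors and the postsynaptic density were at 0.24 in astrocyte-like nuclei (99.98, 11 of 13), with Grin2a at 0.87, and between -0.0026 and 0.02 in the other classes. In the astrocyte class the median was -0.02 with every nucleus weighted alike, and the excitatory (0.43) and oligodendrocyte (0.47) markers were higher as well. Axon guidance and cell adhesion was higher in inhibitory neuron-like nuclei (0.12, percentile 99.96, 24 of 32), with Slit3 at 1.40 and Slit1 at 1.14, and inside the random range elsewhere. In this class the excitatory (0.40) and oligodendrocyte (0.75) markers were also higher and the inhibitory markers lower (-0.24), and after thinning to 1000 UMIs the list lay inside the random range. Voltage-gated ion channels (-0.19, percentile 0.16, 8 of 12 members lower) and neurodevelopmental disorder genes (-0.07, 2.08, 26 of 35) lay below the random lists in oligodendrocyte-like nuclei, in all but 3 of 11 and 5 of 11 settings. In the other classes their medians were inside the random range, and the difference between classes was not tested.

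Heat shock and stress was lower in CA3 pyramidal-like (-0.28, percentile 0.57, 5 of 5 members) and inhibitory neuron-like nuclei (-0.21, 1.14, 7 of 8), with the chaperone gene Hsp90aa1 at -0.55 and -0.40, but in 5 of 10 and 6 of 10 settings the list lay inside the random range. Activity-regulated genes were outside the random range in oligodendrocyte-like nuclei alone (0.51, 99.93, 2 of 3 members higher), where Jun was at 0.79 and Jund at 0.51, and lay inside it in 1 of 9 settings. Myelin genes were at 0.06 in oligodendrocyte-like nuclei, inside the random range (96.3), with Mal at 0.53 and Mobp at -0.13. In neurons that do not make myelin the same list was at 0.32 in dentate granule-like (99.9, 4 members) and 0.34 in CA1 pyramidal-like nuclei (99.8, 3 members). The activated microglia list was at 0.26 in both dentate granule-like (99.7) and oligodendrocyte-like nuclei (98.2), and at 0.12 in microglia-like nuclei (78.9); the first 2 lay inside the random range in 1 of 10 and 3 of 10 settings. Homeostatic microglia genes were at 0.08 in microglia-like nuclei (88.0, 6 of 8 members higher). Astrocyte glutamate and potassium handling was at 0.05 in astrocyte-like nuclei (87.5, 6 of 10), with Aqp4 and Glul at 0.26. The reactive astrocyte list had under 3 members over the floor in every class and gave no value.

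**Figure D4:**
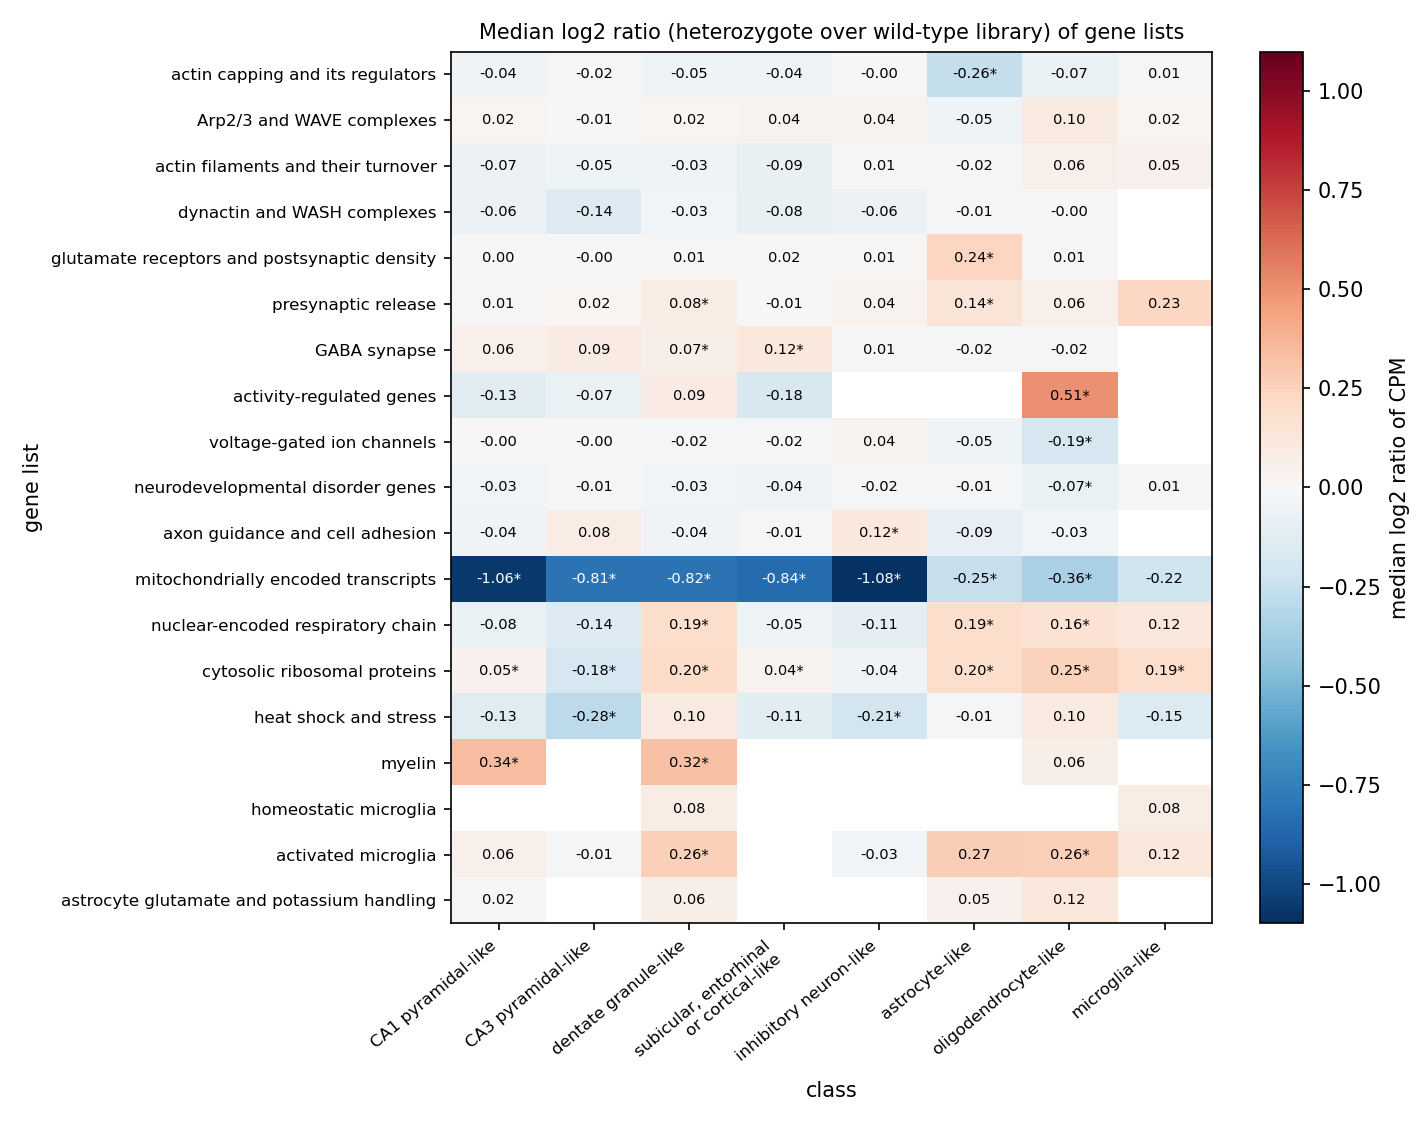
Median log2 ratio (heterozygote over wild-type library) of 19 gene lists in 8 classes; the colour scale and the printed values give the median, an asterisk marks medians outside the range of matched random lists, and blank cells had under 3 members over the floor. Mitochondrially encoded transcripts lie lowest, from -1.08 to -0.22.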

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

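Of the tests below, the spread of Ttr over classes, the choroid plexus list in glial classes alone, the share of the UMIs of the CA1 genes in few nuclei, and the 2 comparisons of depth were chosen after the result they measure was seen. A range given with a median of several genes takes the medians of the bounds of the single genes. It is not an interval of that median. Ranges of depth ratios come from redrawing nuclei. A signal in data outside the named classes was found in 3 places, each higher in the heterozygote than in the wild-type library. Cluster 12 and the mixed clusters still count among the nuclei kept, the denominator of the shares. Barcodes under the gene and mitochondrial filters made up 7.56% (6.99 to 8.17) of the heterozygote against 1.35% (1.09 to 1.66) of the wild-type barcodes, with medians of 535 and 528 UMIs. Cluster 12, unnamed and led by hemoglobin genes, held 3.38% (2.97 to 3.84) against 0.839% (0.619 to 1.11) of the nuclei kept, with 1.45 against 0.125 hemoglobin UMIs per nucleus. Clusters set apart as mixed held 5.05% (4.54 to 5.60) against 2.10% (1.74 to 2.503), but with doublets kept their log2 ratio was -0.04. Each library is also a genotype and a preparation, so these differences cannot be assigned to either.

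Ttr was higher in all 8 classes of the heterozygote library, and free RNA from choroid plexus cells is a candidate source. Its UMIs per nucleus differed between classes by at most 1.69 times (wild type; 1.13 in the heterozygote), while mean UMIs per nucleus differed by 9.51 and 12.3 times, as free RNA would give. Other choroid plexus markers, summed over the 8 classes, had a log2 ratio of 0.20 (0.01 to 0.38), which met both the bound set for this explanation (above 0) and the bound set against it (below 0.5), and wild-type neurons carry these transcripts themselves (up to 0.192 UMIs per nucleus, 0.00446 in the lowest class). In the glial classes alone the same markers were at 1.49 (0.62 to 2.45; 53 against 14 UMIs), the direction free RNA needs. More choroid plexus tissue in 1 dissection and higher Ttr per choroid plexus cell (3.21-fold in CPM over 63 and 14 nuclei, close to the 3.42-fold of the subicular class) both stay open, the second as an untested effect of genotype.

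Genes of other cell classes were higher in the inhibitory and subicular classes of the heterozygote library, and doublets left in it are a candidate explanation, since its automatic doublet threshold marked only 0.0416% of the nuclei. The main comparison removed 5.77% of the heterozygote against 10.94% of the wild-type nuclei as doublets. Free RNA from excitatory neurons is argued against as the whole cause, as the 5 inhibitory class genes, summed over microglia and oligodendrocyte classes, were at -0.13 (-0.32 to 0.06), although the excitatory marker list was higher there (0.21 and 0.25) much as in the inhibitory class (0.40). In the inhibitory class the higher doublet rate in both libraries brought their median from 2.45 to 1.07. Its range (0.79 to 1.49) holds 50% of the first value. The tenth of heterozygote nuclei richest in these genes had 2.28 times (1.84 to 2.70) the UMIs of the others (0.728 in the wild type), as doublets would. With doublets kept Tafa1 was at 0.39 and Hs3st4 at 0.44. With doublets treated alike in both libraries the differences in these genes were thus smaller than in the main comparison. In the subicular class the median stayed at 1.22 (1.06 to 1.38) of 1.75 under the higher rate, the result set against doublets. That rate removes only the highest doublet scores, and doublets with lower scores may remain, so it cannot exclude them. Npy was at -0.03 under this rate, and with doublets kept Glis3 (1.94) was at 0.62 and Zbtb20 (1.55) at 0.65. The depth ratio was 1.98 (1.44 to 2.89) in the heterozygote and 0.909 (0.766 to 1.54) in the wild type. The first has the direction doublets would give, but its lower end fell short of the bound set for them. Whether few nuclei carry the genes was undecided, with at least 65.5% (inhibitory) and 64.5% (subicular) of the UMIs of each gene in the tenth richest in it (typically 44.9% and 46.8%), and an effect of genotype was not tested.

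Unc5d, Efna5, Lrrtm3, Dpp10 and Pcdh15 were lower in the CA1 class of the heterozygote library, and an unequal number of nuclei that carry them is a candidate explanation. In the wild-type library at least 88.1% of the UMIs of each lay in the tenth of nuclei richest in it (typically 44.9%; in the heterozygote the 53 UMIs of Efna5 fix this share at 100%), and nuclei with at least 3 UMIs of 2 or more of the 5 made up 3.38% (26) of the heterozygote and 8.95% (82) of the wild-type class. The genes were picked as the lowest in these nuclei, and a lower level in each nucleus would lower this number as well. It therefore cannot tell fewer carriers from a lower level. A test that weighted 5 parts of nuclei, ranked by the other 4 genes, alike in both libraries left a median of -1.54 of -2.04. This met the bound set against the share of such a subset as the whole cause. Its range (-1.84 to -1.25) was taken over from the unweighted median and is no interval of its own. The richest parts held 226 to 239 wild-type nuclei where at most 131 had 3 UMIs of a gene. They thus mixed carriers with others, so the test cannot separate the share of the subset from the level in each nucleus. The share of the smaller CA1 cluster cannot be told apart, since the median within the larger cluster was -1.08 with a range of -1.83 to -0.02. Whether the subset is a part of CA1 that 1 dissection took less of, cells of another class or an effect of genotype was not tested.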

How the results depend on the processing

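Chosen after the data were examined were the settings with the expected or the higher doublet rate in both libraries, the largest cluster of each class, resolution 2 for expression, and all list and Capza2 (all nuclei) values under the expression settings. Values are log2 ratios, and the cause of a change was not tested unless given.

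The Capza2 ratio over all nuclei stayed below 0 in 10 settings (-0.39 to -0.15), as did 7 of 8 classes. Over all classes and settings 85 of 90 Capza2 values lay within the counting interval. The ratio of shares kept its direction for dentate granule (fold 1.11 to 1.37), CA1 pyramidal (0.674 to 0.823), inhibitory neuron (0.619 to 0.811), oligodendrocyte (1.02 to 1.27), choroid plexus (2.07 to 5.86) and all neurons (0.807 to 0.915) wherever a value was obtained. Of 276 share values 237 lay within the interval, 30 moved and 9 reversed. Of 1229 values of named genes 995 lay within it, 215 moved and 19 reversed. Of 1428 list values 1308 kept their side of the random range, 67 became outside it, 51 no longer were and 2 reversed.

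Shares by setting. At least 200 genes: neurons -0.31, non-neuronal 0.46, excitatory neurons -0.28. At least 1000 genes: -0.14, 0.31 and -0.11, with CA1 pyramidal -0.31 and dentate granule 0.33. Thinned to 1000 UMIs before clustering: neurons -0.13, excitatory -0.10, CA1 pyramidal -0.28, astrocyte 0.39. Doublets kept: non-neuronal 0.39, CA2 pyramidal 0.015, mixed -0.039. Clustered separately: non-neuronal 0.35, endothelial -1.53, subicular 0.55. Against neurons only, which removes the difference in the share of neurons: excitatory 0.026, CA1 pyramidal -0.28, dentate granule 0.45, inhibitory -0.30, subicular -0.40. Against non-neuronal nuclei only: oligodendrocyte 0.035. At most 1% mitochondrial UMIs: CA2 pyramidal 0.20. Resolution 2: CA2 pyramidal -0.16, choroid plexus 1.05. With 3000 variable genes: CA2 pyramidal 0.11, CA3 pyramidal -0.49. Expected doublet rate: CA2 pyramidal 0.21, CA3 pyramidal -0.47, mixed -0.040. Higher doublet rate: CA2 pyramidal 0.17.

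Expression by setting. Nuclei thinned to 1000 UMIs, which leaves few counts: Capza2 -0.29 over all nuclei, 0.46 in CA3 pyramidal and -1.18 in subicular; Capzb 0.16 (inhibitory), Ifi203 -0.083 and Fbxl7 0.42 (CA3 pyramidal), Traip 0.020 (dentate granule), Cntnap2 -0.26 and Kcnip4 -0.19 (astrocyte), presynaptic release -0.0053 (astrocyte). Mean over nuclei: Capza2 -0.15 over all nuclei, Cntnap2 -0.35, Kcnip4 -0.092 and glutamate receptors -0.019 (astrocyte). Largest cluster only: Capza2 -0.77 (subicular), Capzb 0.090 (inhibitory), Stxbp6 -0.21 and Dpp10 0.17 (CA1 pyramidal). At least 1000 genes: Dpp10 0.10 (CA1 pyramidal), Lsamp -0.0011 (microglia). Expected doublet rate: Maml3 -0.032 (CA3 pyramidal), Lsamp -0.87. Higher doublet rate: Npy -0.032 (subicular), Lsamp -0.091. Lsamp was -0.41 with doublets kept and -0.095 with at most 1% mitochondrial UMIs.

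Some settings gave no value: shares of small classes where no cluster was named so in 1 or both libraries (CA2 pyramidal, choroid plexus, mossy, committed precursor, pericyte, macrophage, mixed and unnamed), Cpa6 in the largest subicular cluster, and lists with under 3 members over the floor, mostly after thinning. Thinning left no value for mitochondrially encoded transcripts in CA1, CA3, subicular, inhibitory, astrocyte and microglia classes, so depth limits what can be said of them.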

Other observations

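No test in this part was chosen after the value it measures was seen, though both patterns were noticed in these data first.

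Hspa5 was among the highest genes of the dentate granule-like nuclei, and endoplasmic reticulum chaperones may move together there. The members seen before the test were higher (Hspa5 0.93, Pdia4 0.83, Pdia6 0.71, Pdia3 0.69, Calr 0.68 and Hsp90b1 0.60). The test took 13 further genes of protein handling in the endoplasmic reticulum, not all of them chaperones (Xbp1 encodes a transcription factor). Of these, 13 were higher, with a median log2 ratio of 0.26 at percentile 100 of matched random lists (-0.11 to 0.11). The intervals of Herpud1, Hyou1, Dnajb9, Ero1lb, Dnajc3 and Syvn1 held 0. Those of the further genes that were over the floor elsewhere, partly different ones in each class, were at 0.28 in oligodendrocyte-like (percentile 98.2, 5 members), 0.09 in inhibitory neuron-like (95.3, 9), 0.03 in CA1 pyramidal-like (93.2, 13), -0.03 in CA3 pyramidal-like (73.9, 7) and -0.13 in subicular-like nuclei (17.5, 8). Ribosomal protein genes (0.20 and 0.25) and the nuclear-encoded respiratory chain (0.19 and 0.16) were also higher in dentate granule-like and oligodendrocyte-like nuclei, so the chaperones may share in a wider shift, and cluster 1 held 48.2% of the heterozygote against 30.7% of the wild-type dentate granule-like nuclei. With 1 library per genotype, an effect of genotype, of the mouse and of the preparation cannot be separated.

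The gene model AC149090.1 was higher in all 8 classes of the heterozygote library (0.59 to 2.07, median 1.70). A difference in background between C57BL/6J and C57BL/6N mice could give such a gene, and C57BL/6J carries a deletion in Nnt. The log2 ratio of Nnt over all nuclei was -0.10 (-0.37 to 0.17; 247 against 219 UMIs), but a 3' count outside the deleted part of Nnt would not tell these backgrounds apart, so the test decided nothing and a difference in background stays open. Unlike Ttr, AC149090.1 varied between the classes of a library, by 24.4 times (heterozygote) and 21.2 times (wild type) in UMIs per nucleus. Part of this goes with depth, as mean UMIs per nucleus differed by 12.3 and 9.51 times. In CPM it ran from 366 (oligodendrocyte-like) to 1122 (CA1 pyramidal-like) in the heterozygote. In the wild type it ran from 92.3 (oligodendrocyte-like) to 732 (microglia-like).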
